A study of Mus musculus with 6 samples.

How the data were processed

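RNA-seq of total liver RNA was available for 6 mouse libraries, 3 from wild-type livers (WT_DDC) and 3 from livers with a hepatocyte-specific knockout of Arid1a (Arid1a_KO_DDC). All mice were of mixed C57Bl/6; 129Sv background, 10 weeks old, and had 2 weeks of DDC injury. The groups and replicate numbers came from the sample titles and the genotype label.

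The authors deposited 1 table of log2 FPKM values (fragments per gene, scaled by gene length and by the number of mapped fragments), with 14499 genes and 1 column per library. Per the submitters' processing notes, TopHat2 2.0.6 and Cufflinks were used with the mouse builds mm10 and GRCm38; their order, the gene annotation and the rule for choosing the genes in the table are not given in the sources used here. The lowest deposited log2 value was -10, which marks an FPKM of 0 after an offset of 0.000977 had been added. This offset was checked on 60069 values between 1 and 50: after subtracting it, 100% were numbers of 6 significant digits within a relative tolerance of 3e-08, and 0% were so without subtracting it. The offset was removed and FPKM recovered before any other step. An FPKM of 0 was given for 3664 values, and such a value can be a failed estimate as well as no expression. No table column was left unmatched to a sample.

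FPKM are not counts, so no count model was used. Values were taken to log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 3 of the 6 libraries, whatever their group, were tested, which left 11839 genes. A log2 difference on this scale understates the change of genes with low FPKM. Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values for single genes are from this limma fit. Errors of log2 differences are limma standard errors, and errors of FPKM are SD over the 3 libraries of a group. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1.

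Before the data were examined, 37 gene lists were fixed from general knowledge of liver pathways and cell types, together with the test, the alternatives and the rule for naming genes. The 33 lists with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the members of a list with all other genes tested. The lists were tested again with the correlation estimated for each list, and with fry, which asks whether a list's genes move, on balance, in a single direction without comparing them with other genes. Where a symbol had several rows, as was so for 11 names, the row with the highest mean FPKM stood for it.

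The genes named are of 3 kinds. Arid1a, Ctgf, Cyr61, Ankrd1, Krt7, Krt19, Epcam, Sox9 and Spp1 were named whatever their values. The 12 largest rises and 12 largest falls were named among genes past the threshold with groups that did not overlap and a mean of at least 5 FPKM in the higher group, leaving out predicted and clone names. For gene lists described, up to 4 members with the smallest p were named; further genes are said to be chosen after their values were seen. Gene positions are from GENCODE M21 on GRCm38, in which 14453 of the 14499 gene identifiers were found.

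The fragment number of each library was not used here. Steps between low values (under 0.3 FPKM) allowed only a comparison of depth with WT_DDC replicate 1, so no counting intervals are given. Nothing in the labels states a sequencing batch, but library identifiers fall into L0566 and L0567 (replicate 1 of both groups) and L0602 to L0605 (all others). That split was used as an added term and as a subset. Alternatives were a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, eBayes without the trend or with robust estimation, a replicate block, a term for the library numbers, the 4 libraries L0602 to L0605 alone, leaving out each library, and other list tests. Leaving out immunoglobulin genes, and an estimated correlation together with the library number term, were added after seeing the data.

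The fit was tested on simulated data for the comparison of knockout with wild type, with the means of the real genes and normal noise of the variances moderated by limma. The changed genes were drawn only from those above a set mean expression, so recovery of genes with low FPKM was not tested. Of 100 genes changed by 1 log2 unit, 57 were recovered, and of 100 changed by 2 log2 units, 96 were, among 11631 genes tested. Of the 164 genes called, 11 had not been changed. The simulation drew genes independently, so it does not test how camera behaves when the genes of a list vary together. Figures were drawn with matplotlib.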

Results

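RNA-seq was used to compare wild-type mouse livers with livers lacking Arid1a in hepatocytes after 2 weeks of DDC, a porphyrinogenic compound that injures the liver and brings a ductular reaction. Arid1a encodes a DNA-binding subunit of the BAF chromatin remodelling complex. Each genotype had 3 libraries, and the comparison asks which injury-time transcripts, among them YAP target genes, depend on the genotype. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries. Between 11280 and 11712 genes per library had an FPKM of at least 1. Relative to WT_DDC replicate 1, the estimated depth of the other libraries was 0.904 to 1.16, and absolute depth is unknown. Pearson correlations across genes, which are not independent replicates, were 0.947 to 0.971 within wild type, 0.946 to 0.961 within knockout and 0.932 to 0.953 between the groups.

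The Y-linked genes Ddx3y and Eif2s3y were near 0 in replicate 1 of both groups, with Ddx3y at 0.0527 and 0.0227 FPKM, and were expressed in replicates 2 and 3, with Ddx3y between 9.27 and 11.3 FPKM. This split coincides with the library identifiers and is balanced over genotype. The first principal component held 33.5% of the variance and separated the genotypes, and the next held 29.4% and separated replicate 1 of both groups from the other libraries.

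Arid1a itself (ENSMUSG00000007880, chromosome 4, 133679008 to 133756769 on GRCm38, protein coding) was at 6.44 ± 1.25 FPKM in wild-type and 5.14 ± 1.41 FPKM in knockout livers (SD, n = 3 libraries each; exact permutation p = 0.4). The log2 difference was -0.29 (SE 0.22, limma adjusted p = 0.678), and the groups overlapped. A gene-level FPKM also covers exons outside the deleted part and cells other than hepatocytes, so it does not check the labels. The 22 tested BAF complex subunits had a median log2 difference of -0.03 and no member past the threshold (camera adjusted p = 0.916).

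Knockout livers had higher transcripts of several interferon-stimulated genes, and lower transcripts of several MHC class II, chemokine and biliary genes. In all, 16 genes were higher and 42 lower in knockout livers among 11839 tested. At the pseudocount of 1 the largest rise among named genes was that of Cdhr2, a protocadherin of the brush border, from 0.239 ± 0.0417 to 7.53 ± 2.62 FPKM (log2 difference 2.74, SE 0.25, adjusted p = 0.0171); it was 1.24 with a pseudocount of 5 and 4.44 with 0.1. Hsd17b6, a hydroxysteroid dehydrogenase, rose from 51.2 ± 13.6 to 256 ± 60.8 FPKM (2.31, SE 0.27, adjusted p = 0.0293), and its rise was 2.08 to 2.52 over all alternatives. Fabp1, the main fatty acid binding protein of hepatocytes, rose from 1308 ± 314 to 4126 ± 219 FPKM (adjusted p = 0.0381). Apoc2, the cofactor of lipoprotein lipase, rose by 1.38 log2 units, Fabp2 by 1.17 and Etnppl, which degrades phosphoethanolamine, by 1.39 (adjusted p = 0.0386, 0.0268 and 0.0453).

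**Figure D1:**
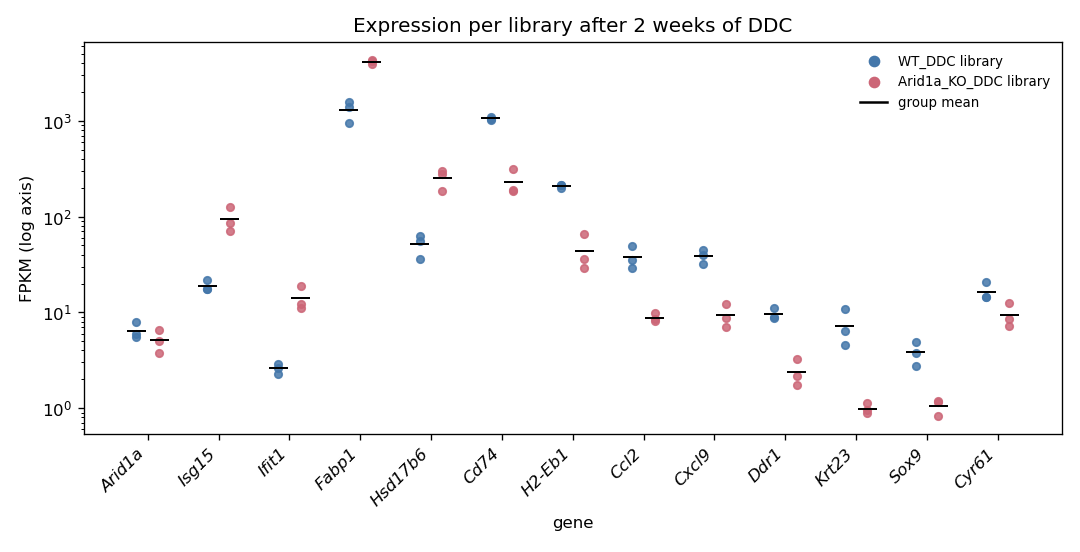
FPKM on a log axis of 13 genes in 3 WT_DDC and 3 Arid1a_KO_DDC libraries; points are libraries and lines are group means. Cd74, H2-Eb1, Ccl2, Cxcl9, Ddr1 and Krt23 had no overlap between the groups and were lower in knockout, Isg15, Ifit1, Fabp1 and Hsd17b6 were higher, and Arid1a overlapped.

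Among the falls, Hamp2, a hepcidin gene, fell from 334 ± 117 to 23.6 ± 11 FPKM (log2 difference -3.81, SE 0.43, adjusted p = 0.0274). Its paralog Hamp had a log2 difference of -0.28 (adjusted p = 0.928), and reads shared between the paralogs make the value of Hamp2 uncertain. Tgtp1, an interferon-inducible GTPase, fell by 3.52 log2 units (SE 0.25, adjusted p = 0.0128), with a near-identical neighbour, Tgtp2, at -1.37 (adjusted p = 0.118), so the share of reads between the pair is uncertain too. Cib3, a calcium-binding protein gene, fell by 3.14 (adjusted p = 0.0188), Slc13a3, a dicarboxylate transporter, by 2.87 (adjusted p = 0.0381) and Pde9a, a cyclic GMP phosphodiesterase, by 2.72 (adjusted p = 0.0128). The remaining named falls were 6 immunoglobulin variable genes, described with the B cell markers, and H2-Eb1.

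All 58 genes past the threshold had groups that did not overlap. Over all genes tested, 16.6% had groups that did not overlap, against 10% by chance, and 1320 genes had an unadjusted p under 0.05, against 592 by chance. These counts changed with the library left out, and each such fit also has fewer libraries from which to estimate the spread. The log2 differences moved less, for example 1.99 to 2.41 for Isg15 and -2.51 to -2.11 for Cd74 with 1 library left out. Leaving out WT_DDC replicate 1 gave 9 higher and 26 lower genes, and leaving out WT_DDC replicate 2 gave 0 and 6. Leaving out WT_DDC replicate 3 gave 0 and 2, and leaving out Arid1a_KO_DDC replicate 1 gave 30 and 37. Leaving out Arid1a_KO_DDC replicate 2 gave 6 and 40, and without Arid1a_KO_DDC replicate 3 limma called 0 in either direction, with 391 higher and 527 lower at an unadjusted p under 0.05.

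Several genes of the interferon response rose in knockout livers, and the list was higher at the preset correlation. Isg15, a ubiquitin-like modifier, rose from 18.9 ± 2.33 to 94.1 ± 29 FPKM (log2 difference 2.22, SE 0.23, adjusted p = 0.0214), and Ifit1, an RNA-binding antiviral protein, rose from 2.6 ± 0.293 to 14.1 ± 4.25 FPKM (2.04, SE 0.21, adjusted p = 0.0215). Oas1a and Ifit3 rose by 1.92 and 1.71 log2 units (adjusted p = 0.0331 and 0.0381), and Ifi44 by 1.70. Of 24 tested members, 5 rose and 0 fell over all genes, and 15 rose and 3 fell adjusted over the list alone. The list had a median of 0.996 and passed camera (adjusted p = 1.91e-09), but not with the correlation estimated from the data (adjusted p = 0.515 with an estimated correlation) and not in fry (adjusted p = 0.0895).

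Several genes of MHC class II antigen presentation fell, and the list was lower at the preset correlation and in fry. Cd74, the invariant chain, fell from 1061 ± 37.6 to 230 ± 75.8 FPKM (log2 difference -2.25, SE 0.23, adjusted p = 0.0214). H2-Eb1 fell by 2.32 log2 units (adjusted p = 0.0331), H2-DMa by 1.90 (adjusted p = 0.0214) and H2-Aa by 1.88 (adjusted p = 0.0364). Of 12 tested members 5 fell over all genes and 10 adjusted over the list alone, with a median of -1.21 (camera adjusted p = 5.12e-12; adjusted p = 0.437 with an estimated correlation). Chemokine and cytokine genes had a median of -0.77. Ccl2, a monocyte attractant, fell from 37.8 ± 10.3 to 8.84 ± 0.899 FPKM (-1.95, SE 0.21, adjusted p = 0.0231), and Cxcl9, which is induced by interferon-gamma, by 1.96 (adjusted p = 0.0277). Ccl5 and Vcam1 had differences of -1.02 and -0.67 and did not pass over all genes (adjusted p = 0.0901 and 0.104). Of 20 tested members 2 fell over all genes, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.9e-10; adjusted p = 0.437 with an estimated correlation).

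Of the biliary and progenitor markers 3 single genes fell, and the list was lower at the preset correlation. Ddr1, a collagen receptor, fell from 9.57 ± 1.29 to 2.38 ± 0.777 FPKM (log2 difference -1.66, SE 0.20, adjusted p = 0.0317). Cldn4, a tight junction protein, fell by 1.42 (adjusted p = 0.0386) and Krt23, a keratin, by 1.99 (adjusted p = 0.0447). Sox9, a transcription factor of biliary and progenitor cells, was at 3.83 ± 1.09 and 1.05 ± 0.203 FPKM, did not overlap between the groups and did not pass over all genes (-1.21, SE 0.20, adjusted p = 0.0815). Epcam, Krt19 and Krt7 had differences of -0.67, -0.61 and -0.58 (adjusted p = 0.307, 0.638 and 0.613), and Spp1 of 0.28 (adjusted p = 0.868). Krt19 was at -0.30 and Krt7 at -0.22 without WT_DDC replicate 2, and Krt19 at -1.08 without WT_DDC replicate 1 and Krt7 at -0.85 without Arid1a_KO_DDC replicate 3. Of 19 tested members 3 fell over all genes and 7 adjusted over the list alone. The list passed camera with a median of -0.58 (adjusted p = 3.46e-07), not with the correlation estimated (adjusted p = 0.515 with an estimated correlation) and not in fry (adjusted p = 0.14).

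YAP target genes, named in the series title, did not pass as a list or as single genes. These are levels in total liver RNA, which also holds cells other than hepatocytes, so they do not show YAP targets in hepatocytes alone. Of 17 tested members 13 had a negative difference, with a median of -0.16, and 0 passed over all genes or adjusted over the list alone by limma (camera adjusted p = 0.0792; adjusted p = 0.745 with an estimated correlation). Cyr61 (chromosome 3, 145646976 to 145649981), a matricellular protein gene, was at 16.5 ± 3.64 and 9.37 ± 2.75 FPKM with groups that did not overlap (log2 difference -0.77, SE 0.24, adjusted p = 0.296). Ctgf was at 8.73 ± 1.02 and 8.42 ± 2.71 FPKM (-0.08, SE 0.22, adjusted p = 0.923), and Ankrd1 was near 1 FPKM in both (-0.30, SE 0.32, adjusted p = 0.776; -0.62 without WT_DDC replicate 1 and -0.13 without Arid1a_KO_DDC replicate 3). Myof and Crim1 had differences of -0.53 and -0.35, and Nt5e of 0.68 (adjusted p = 0.369, 0.472 and 0.478). Nt5e was at 0.44 without WT_DDC replicate 2 and at 1.01 without WT_DDC replicate 1. The list passed camera without WT_DDC replicate 2 (adjusted p = 0.0477), without Arid1a_KO_DDC replicate 1 (0.00948), with no filter (0.0272) and in the libraries L0602 to L0605 alone (0.0467), within a range of 0.00948 to 0.745 over all alternatives. The Hippo pathway components had a median of -0.0028 (camera adjusted p = 0.962).

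Some lists of other liver cells and of matrix and Notch genes were lower at the preset correlation, and none of these with the correlation estimated. Stellate cell and fibroblast markers had a median of -0.43 over 19 tested members, with Pdgfra at -0.74 and Acta2 at -0.81, or -0.51 without Arid1a_KO_DDC replicate 3 (camera adjusted p = 0.000227; adjusted p = 0.554 with an estimated correlation). Macrophage and monocyte markers had a median of -0.30 over 17, with Csf1r at -0.77 and Lyz2 at -0.86 (adjusted p = 0.0128; adjusted p = 0.673 with an estimated correlation). Sinusoidal endothelial markers had a median of -0.33 over 13, with Stab1 at -0.61 (adjusted p = 0.023; adjusted p = 0.758 with an estimated correlation). TGF-beta and extracellular matrix genes had a median of -0.37 over 20, with Itgav at -0.72 and Mmp14 at -1.26 (adjusted p = 0.00109; adjusted p = 0.515 with an estimated correlation). Notch pathway genes had a median of -0.22 over 7, with Hes1 at -0.86 (adjusted p = 0.036; adjusted p = 0.737 with an estimated correlation). No single member of these 5 lists passed over all genes, and Hes1 was the 1 member that passed adjusted over the list alone. The macrophage list no longer passed without WT_DDC replicate 1 (adjusted p = 0.073) or Arid1a_KO_DDC replicate 3 (0.176). The sinusoidal and Notch lists no longer passed without WT_DDC replicate 1 (0.127 and 0.208), Arid1a_KO_DDC replicate 2 (0.148 and 0.11) or Arid1a_KO_DDC replicate 3 (0.429 and 0.176), nor the sinusoidal list without WT_DDC replicate 3 (0.123).

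Some metabolic lists and the cell cycle list were higher at the preset correlation, and none of these with the correlation estimated. NRF2 and glutathione genes had a median of 0.46 over 19 members. Gstm2, a glutathione transferase, rose from 346 ± 38.2 to 756 ± 83.5 FPKM (adjusted p = 0.0486), and Gsta4 and Gsta2 were at 0.81 and 1.03 (adjusted p = 0.0827 and 0.108). The list had 1 member past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 4.35e-06; adjusted p = 0.515 with an estimated correlation). Cell cycle genes had a median of 0.31 over 25, with Tyms at 0.92 and Rrm2 at 1.19 (adjusted p = 0.000332; adjusted p = 0.515 with an estimated correlation). Bile acid genes had a median of 0.36 over 23, with Cyp8b1, the sterol 12-alpha-hydroxylase, at 2.19 and the exporter Abcc3 at -0.82 (adjusted p = 0.00841; adjusted p = 0.745 with an estimated correlation). Fatty acid synthesis genes had a median of 0.19 over 18, with Elovl6 at 0.70 (adjusted p = 0.023; adjusted p = 0.554 with an estimated correlation), and fatty acid oxidation genes 0.13 over 20, with Acaa1b at 1.27 (adjusted p = 0.0303; adjusted p = 0.745 with an estimated correlation). Of these last 4 lists, 0 members passed over all genes by limma; adjusted over the list alone, 1 bile acid gene rose and 1 fell, and 1 fatty acid oxidation gene rose. The bile acid list no longer passed without Arid1a_KO_DDC replicate 3 (adjusted p = 0.23), the fatty acid synthesis list without WT_DDC replicate 2 (0.224), and the fatty acid oxidation list without WT_DDC replicate 1 (0.0555), WT_DDC replicate 3 (0.103) or Arid1a_KO_DDC replicate 3 (0.429). Hepatocyte secreted and metabolic genes had a median of 0.11 over 22 and did not pass (camera adjusted p = 0.116); the list passed without WT_DDC replicate 3 (0.0486) or Arid1a_KO_DDC replicate 1 (0.00163), and changed direction without Arid1a_KO_DDC replicate 3 (0.747).

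**Figure D2:**
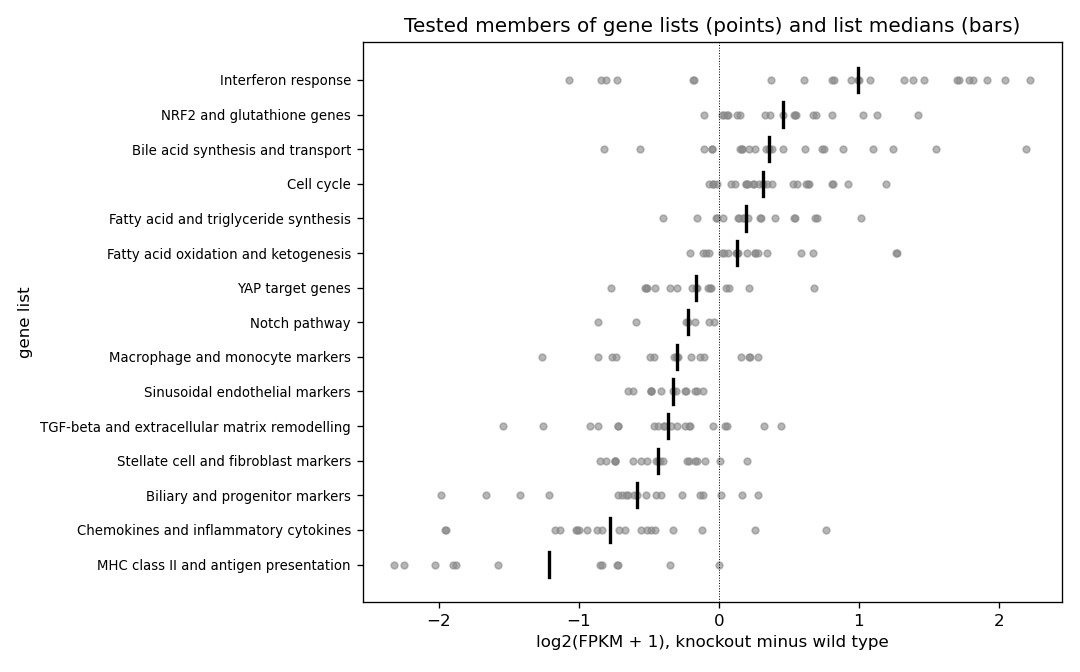
Log2 difference, knockout minus wild type, of the tested members (points) of the 14 lists past camera at a preset correlation and of the YAP target genes, with each list's median (bar). Medians ran from -1.21 for MHC class II to 0.996 for the interferon response.

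In all, 14 of 33 lists passed camera at the preset correlation, 8 down and 6 up. With the correlation estimated 0 passed, the lowest adjusted p being 0.437, and in fry the MHC class II and chemokine lists passed (adjusted p = 0.0345 each). Every other split of the same 6 libraries also gave lists past the preset camera, from 7 to 15 of them. That count therefore does not set the genotypes apart from other groupings, and a small p at the preset correlation is not particular to genotype. The other 19 lists had adjusted p-values of 0.0582 to 0.962. The sign of the camera result differed from that of the median in 1 of the 33 lists and from that of the mean in 2. The p53 and senescence list had a median of -0.03 with camera up, the cytochrome P450 list a mean of -0.0024 with camera up and the fetal liver list a mean of 0.22 with camera down.

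Transcripts of B and plasma cells differed widely between the knockout libraries. The list of B and plasma cell markers had a median of -0.41 over 6 members and did not pass (camera adjusted p = 0.182), but passed without Arid1a_KO_DDC replicate 2 (adjusted p = 4.54e-08). Igkc, the kappa constant gene, was at 1478, 4001 and 5412 FPKM in the wild-type libraries and at 17.6, 7538 and 22.5 FPKM in knockout replicates 1, 2 and 3. Of 64 immunoglobulin genes tested 6 fell and 0 rose. Igkv12-44 had 118, 122 and 467 FPKM in wild type and 0.596, 0 and 0 in knockout (adjusted p = 0.0128), and Ighv8-5 was listed at 0 in all 3 knockout libraries and at 24.2, 46.0 and 102 FPKM in wild type (adjusted p = 0.0136). Variable genes of the same family are similar in sequence, so the share of reads between them is uncertain.

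**Figure D3:**
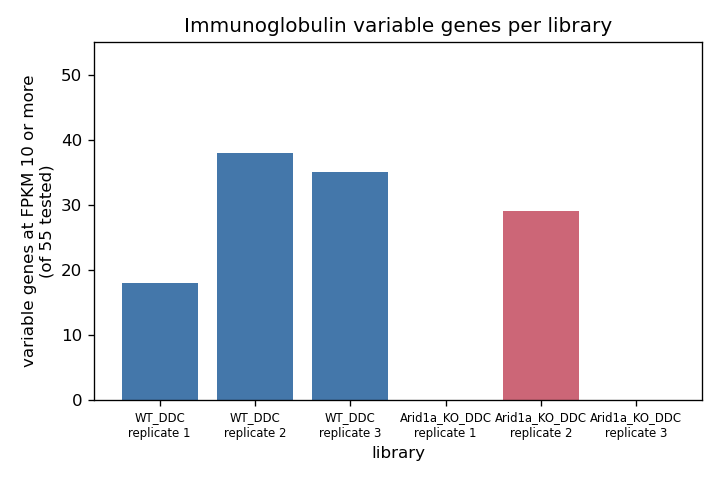
Number of immunoglobulin variable genes, of 55 tested, with an FPKM of at least 10 in each library. Wild-type libraries had 18, 38 and 35, and knockout replicates 1, 2 and 3 had 0, 29 and 0.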

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

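Replicate 1 of both groups, which lacks Y-linked transcripts, and replicates 2 and 3 had knockout minus wild type differences of unlike sign for 9 named genes whose groups did not overlap in replicates 2 and 3, although in replicate 1, 1 library per group, that of Krt19, Anxa5 and Ccne1 was near 0 (0.02, 0.02 and -0.02). The difference between the knockout effects, as an interaction term in limma on the log2 scale, was -0.93 for Ctgf, -0.91 for Ankrd1, -0.95 for Krt19, 1.71 for Abcg5 and -0.995 for Pecam1. It was -1.47 for Fcgr2b, 1.41 for Mcm5, 1.24 for Ccne1 and -1.03 for Anxa5. None of the 9 passed adjustment over all genes (adjusted p = 0.335 to 0.619), and 0 of 11839 genes did in limma, with 1072 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0652. By chance 592 genes would be expected at that unadjusted level, so an interaction over many genes is not excluded. Genes are not independent, however, and replicate 1 is a single library per group. Sex and library number cannot be separated in these samples.

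The tests of MHC class II against cell lists, strain and hepatocyte RNA were chosen after the falls had been seen. The rules for hepatocyte RNA and for strain on chromosome 17 were made stricter after their values were seen, which moved the first from supported to open and the other from excluded to open. The tests of interferon-gamma genes, constant genes, clones and the library split were written before their own test values were seen. They still address patterns found in these same data. For the interferon-gamma test, 5 of its 11 genes belong to the interferon response list, whose rise is part of the pattern addressed. Its mean is therefore not independent of that pattern. MHC class II genes were lower by 1.69 log2 units as a mean of 8 genes; a different MHC haplotype in the mixed strain background would leave those outside chromosome 17 in place, yet the mean of Cd74, Ciita and Ctss had a difference of -1.27 (SE 0.21), and that of Ciita and Ctss without Cd74 -0.78 (SE 0.23). For the class II genes on chromosome 17 a haplotype or linked strain region stays open: 6 of them fell as a mean by 0.48 (SE 0.21) more than those outside it. Of the 58 genes past the threshold 9 lie on that chromosome, 5 of them H2 genes, against 2.88 expected, and all 9 fell. The two-sided Fisher's exact test gave p = 0.00208, or 0.0457 adjusted over chromosomes, and was chosen after the calls were seen. With H2 genes and the class II list left out, 4 of 381 tested genes within 20 Mb of H2-Eb1 passed, against 1.68 expected (two-sided Fisher's exact test p = 0.0865). These were Pde9a, Cyp4f16, Ddr1 and Pla2g7, all lower in knockout, of which Cyp4f16 and Pla2g7 were chosen after their values were seen. Fewer antigen-presenting cells stay open: the class II mean fell by 1.37 (SE 0.32) beyond the macrophage mean, but its difference from the B and plasma cell mean was -0.75 (SE 0.65). That wide error comes from knockout replicate 2. Its B and plasma cell mean was 3.59, above the 2.75 to 2.79 of wild type, while its class II mean was 4.63 against 5.78 to 5.88. In this 1 library class II genes were lower without fewer B cell transcripts. In knockout replicates 1 and 3 the B and plasma cell mean was lower too, at 1.05 and 0.83. A candidate explanation is a lower interferon-gamma response beside a higher type I response: the mean of 11 interferon-gamma induced genes was -0.66 (SE 0.23), although 0 of the 11 passed over all genes in limma and 5 of them are also members of the interferon response list.

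The fall of 6 immunoglobulin variable genes has 2 open explanations; the mean difference of the 55 variable genes tested was -2.47 with an SE of 1.51, and their sum in knockout replicate 2, 10521 FPKM, was above the 1866 to 8045 FPKM of the wild-type libraries. With fewer plasma and B cells, constant genes would fall too, and their mean was at -2.98 with an SE of 2.11, since knockout replicate 2 was at 7.33 on the log2 scale against 5.03 to 7.31 in wild type and 1.19 and 1.47 in the other two knockout libraries. With a few expanded clones per liver, a minority of variable genes would separate the groups and the variable genes would spread more than the constant ones. That was so, with 32.7% lower in all knockout libraries and a median SD of 1.78 against 0.907 in wild type. But the variable genes summed to only 21.9 and 25.6 FPKM in knockout replicates 1 and 3, so which genes separated rested mainly on knockout replicate 2. These values therefore cannot tell clones from fewer plasma and B cells. Against a few clones, each wild-type library had 18 to 38 variable genes at 10 FPKM or more. Of the 55 variable genes, 17, 3 and 1 were listed at 0 in WT_DDC replicates 1, 2 and 3. Whether such low levels add to the spread of variable genes was not tested, so the larger spread does not by itself point to clones.

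Of 6 lists of markers of cells other than hepatocytes, the biliary, stellate, macrophage and sinusoidal lists were lower in camera at the preset correlation but not with it estimated (adjusted p = 0.515 to 0.758), and the T and NK list (0.0582) and the B and plasma list (0.182) did not pass at the preset correlation with all 6 libraries. Without Arid1a_KO_DDC replicate 2 both passed as lower (8.33e-05 and 4.54e-08), and without Arid1a_KO_DDC replicate 3 the macrophage (0.176) and sinusoidal (0.429) lists did not; nor did they without WT_DDC replicate 1 (0.073 and 0.127), nor the sinusoidal list without WT_DDC replicate 3 (0.123) or Arid1a_KO_DDC replicate 2 (0.148). If the library number and sex split made the fall of the biliary list, the fall would end in the libraries L0602 to L0605 alone. There its camera adjusted p was 6.73e-08 at the preset correlation, within a range of 1.07e-10 to 0.621 over all alternatives. The split is balanced over genotype and could not by itself make such a fall, so this outcome excludes nothing. The biliary list mean was 2.73 in wild-type and 2.55 in knockout replicate 1. In replicates 2 and 3 it was 3.37 and 3.18 in wild type and 2.46 and 2.45 in knockout. A larger share of hepatocyte RNA would lower all lists alike. The largest difference between 2 of the 6 lists was 0.939 standard errors, but only 2 of the 6 lists were lower by more than 2 standard errors, so like and unlike falls cannot be told apart with 3 libraries a group.

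The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 58 genes and the highest other split 1, so 1 split of the 10, the real one, gave as many; the counts of 16 higher and 42 lower stood against 1 in the larger direction of any other split. For gene lists 2 of the 10 splits gave as many as the real 14, the other one, with 15, placing replicate 1 of both groups and WT_DDC replicate 3 together. With a term for the library numbers the 14 lists again passed in their direction at the preset correlation, and 0 passed with the correlation estimated.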

How the results depend on the processing

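The alternatives with immunoglobulin genes left out, and with an estimated correlation and library number term together, were chosen after seeing the data. Causes were not tested unless fewer libraries or genes are named. Of 32 named genes past the threshold 0 reversed, and all 32 lost the call in at least 1 alternative, since the replicate block and the fit without Arid1a_KO_DDC replicate 3 called 0 genes. Of the 14 lists past camera 0 reversed, but with the filter at 5 FPKM and with quantile normalization 10 stayed past. The bile acid list had an adjusted p of 0.0691 and 0.0529 in these, fatty acid oxidation 0.0691 and 0.154, fatty acid synthesis 0.0815 and 0.095, and Notch 0.0872 with quantile normalization and 0.0552 with a pseudocount of 5; with the filter it had too few members to be tested. The count of 16 higher genes became 10 with no filter, 33 with the library number term and 26 in the libraries L0602 to L0605 alone. With 1 library left out it ran from 0 to 30, and the 42 lower genes ran from 0 to 40. The count of 42 lower genes became 30 with no filter, 59 with the library number term and 37 in the libraries L0602 to L0605 alone. With immunoglobulin genes left out 19 were higher and 37 lower. The Arid1a difference kept its sign and did not pass, from -0.46 to -0.12 over all alternatives.

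The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.346, 0.133 and 0.0212, and only replicate 1 correlated best with its own number. With a replicate block limma called 0 genes higher and 0 lower, with 776 and 942 at an unadjusted p under 0.05. Under that block lists not past camera changed direction, at adjusted p = 0.975 for Hippo components, 0.909 for adipocyte markers and 0.647 for fetal liver genes, and T and NK cell markers passed (0.0243), as they did with no filter (0.00272), a pseudocount of 0.1 (0.0444) and camera on ranks (0.0307).

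The biliary list had an adjusted p of 0.515 with an estimated correlation, 0.14 in fry and 0.621 with an estimated correlation and library number term. The YAP list passed with no filter (0.0272) and in the libraries L0602 to L0605 alone (0.0467), and ran from 0.00948 to 0.442 with 1 library left out. Ctgf ran from -0.30 to 0.0907, Spp1 from -0.22 to 0.62 and Cd79b from -0.67 to 0.10 with 1 library left out, and Spp1 was at -0.13 in L0602 to L0605 alone.

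The remaining changes of direction were in lists that did not pass, given as adjusted p. BAF subunits were at 0.927 with quantile normalization. Hippo components were at 0.941 with a pseudocount of 5, 0.935 with the filter at 5 FPKM, 0.744 with quantile normalization and 0.979 with camera on ranks. Cytochrome P450 genes were at 0.722 with quantile normalization, and cholesterol genes, up and past the threshold, at 0.0276 in L0602 to L0605 alone and at 0.000814 without WT_DDC replicate 1, but down and past it at 0.00034 without WT_DDC replicate 2. In L0602 to L0605 alone the hepatocyte (0.00861), periportal (0.00924), cytochrome P450 (0.0065) and male-biased (0.0109) lists also passed. Adipocyte markers were at 0.892 with the library number term and 0.955 with an estimated correlation added. Fetal liver genes were at 0.992 with a pseudocount of 0.1 and 0.306 with no filter. With 1 library left out the ranges were 0.542 to 0.947 for BAF subunits, 0.303 to 0.955 for Hippo components, 0.00163 to 0.747 for hepatocyte genes, 0.0234 to 0.921 for cytochrome P450, 0.00034 to 0.573 for cholesterol, 0.342 to 0.991 for adipocyte markers, 0.0875 to 0.849 for acute phase, 0.342 to 0.951 for fetal liver and 0.00033 to 0.925 for male-biased genes. Absolute depth is unknown, so a gene listed at 0 has no limit given.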

Other observations

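Of 13 tested pericentral genes 0 passed over all genes by limma, with 4 at an unadjusted p under 0.05, and Slc1a2 and Oat passed adjusted over the list alone. The glutamate transporter gene Slc1a2 was at 4.86 ± 2.98 FPKM in wild-type and 0.223 ± 0.115 FPKM in knockout livers (log2 difference -2.15, limma adjusted p = 0.0662), and Oat, ornithine aminotransferase, at 138 ± 34.8 and 46.3 ± 10.3 FPKM (-1.55, adjusted p = 0.0738). The list did not pass (median -0.16, camera adjusted p = 0.116; 0.745 with an estimated correlation; 0.0381 without WT_DDC replicate 2 and 0.0416 without Arid1a_KO_DDC replicate 3). Periportal genes had a median of 0.16 over 14 (camera adjusted p = 0.0629), and passed without Arid1a_KO_DDC replicate 1 (0.00413) or WT_DDC replicate 3 (0.0486) and in L0602 to L0605 alone (0.00924); its member Etnppl passed over all genes (adjusted p = 0.0453).

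Among fetal liver genes, H19, an imprinted noncoding RNA, was at 6.57, 3.02 and 7.47 FPKM in wild type and at 41.0, 79.5 and 14.1 FPKM in knockout (log2 difference 2.54, SE 0.60, adjusted p = 0.181), and Cd44 had a difference of -0.79 (adjusted p = 0.205). Afp was at 0.74 (adjusted p = 0.357). Chosen after their values were seen, Igf2, which lies beside H19, had a difference of 1.41 (adjusted p = 0.42) and Cdkn2a, a senescence gene, of -1.09 with groups that did not overlap (adjusted p = 0.0859). Of the erythroid markers, too few to test as a list, Alas2 was at 16.6 ± 12.5 and 79.5 ± 40.1 FPKM (adjusted p = 0.285).

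Within 20 Mb of Arid1a, 1 of 385 tested genes was past the threshold, against 1.89 expected (two-sided Fisher's exact test p = 1). The mitochondrial gene mt-Atp8 was at 88549 FPKM in WT_DDC replicate 1 and between 516348 and 842636 FPKM in the other libraries.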
